A study of Mus musculus with 6 samples.

How the data were processed

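Gene expression was measured by RNA-seq in colonic tissue of 6 libraries, 3 from mice labelled DSS and 3 from mice labelled DSS and DCA. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected with oligo(dT), the second strand was marked with dUTP and paired reads were sequenced. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without giving the role of each. The genome build and any use of strand in counting are not given in the sources used here.

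The deposited table gives FPKM per gene and library, per the file headers, that is fragments scaled to transcript length and to the mapped total of the library, with no stated scaling between libraries. The authors' fold is given as a ratio of DSS+DCA over DSS, and in the deposited table it equals the ratio of the mean FPKM of the groups where both means are at least 0.5. The log2 of that fold is deposited in a further column, per the file headers. The p-values and q-values of the authors' own comparison are deposited too, per the file headers, and the tool that made them is not given in the sources used here. The authors' columns were used only to describe the deposited calls and their overlap with those made here.

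Whole reads were not recovered from the FPKM. The step between low values, multiplied by transcript length, implied 15300000 to 18400000 fragments per library, but only 25.2% to 31.1% of low values lay within 0.05 fragments of a whole number, where chance gives 10%. The planned count tests therefore did not apply, and the planned test for FPKM was used. The table held 36977 genes, of which 36870 identifiers were in the GENCODE M21 annotation, and 134 identifiers shared a symbol with another. One of 2 Septin2 identifiers was listed at 20.0 FPKM in DSS replicate 1 and at 0 in the other 5 libraries, so a value of 0 was read only as listed at 0.

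Values were transformed to log2(FPKM + 1), and the 14611 genes with a mean of at least 0.5 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, without covariates. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Log2 changes are on this scale and understate the change of low genes, while folds in the text are ratios of mean FPKM. Errors of means are SD over 3 libraries and errors of log2 changes are SE. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists with at least 3 tested genes, and again with an estimated correlation, with which 0 of the 18 calls held (smallest adjusted p = 0.795). Fry called 0 of the lists for a change on balance in one direction (smallest adjusted p = 0.131) and 21 for a change in either direction.

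The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes that separated the groups and had a mean of at least 1 FPKM in the higher group, passing over predicted genes. In each list with a called member it took up to 4 members of smallest p, and 3 in a list called by camera without such a member. To these it added Il1b, Il6, Tnf, Nr1h4, Gpbar1, Slc51a, Slc51b, Fgf15, Lgr5, Muc2, Reg3g, S100a8, S100a9, Mki67, Tjp1 and Ocln. One gene that the rule took is not reported here.

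The script was tested on simulated data for the DSS+DCA against DSS comparison, with 14611 genes, 200 of them changed, in 5 runs. The changed genes were drawn from those with a mean log2 value above 2. With 3 libraries against 3 it recovered 14.3%, 66.0% and 87.9% of genes changed by 1, 2 and 3 log2 units, with 7 false calls on average. With DSS replicate 4 left out it recovered 0.299%, 38.8% and 75.8%, with 2.8 false calls. In 10 runs, camera found 10 of 10 lists of 20 genes shifted by -1 and 0 of 10 unshifted lists. Libraries were simulated as independent and with equal spread, while in the data DSS replicate 4 lay at the mean of DSS replicates 1 and 2. The recovery and false calls, with and without DSS replicate 4, may therefore not hold for these data. Genes were simulated without correlation between them, so these runs did not test how often camera calls lists of correlated genes. In the data the estimated correlation reached 0.961, for smooth muscle markers.

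Alternatives were a pseudocount of 0.1, no filter, a mean of at least 2 FPKM, TMM-style scaling (trimmed mean of M values, computed on the FPKM), quantile normalization, array weights, the replicate number as a block, an adjusted p under 0.1, a minimum fold of 2, and leaving out each library. Rescaling FPKM to an equal sum over protein-coding genes outside the mitochondrial genome was added after seeing the data. Enrichment used the terms deposited with the table that held 10 to 500 of 12071 annotated tested genes, with a one-sided hypergeometric test. Tables were read with data.table version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.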

Results

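Bulk RNA-seq of colonic tissue was deposited for 6 libraries from mice with colitis induced by dextran sodium sulfate (DSS), a polysaccharide that injures the colonic epithelium. The DSS group and the DSS+DCA group held 3 libraries each, numbered 1, 2 and 4. The protocol label, worded alike for all 6 samples, gives 2% DSS over 7 days and then an enema of deoxycholic acid (DCA), a secondary bile acid formed by gut bacteria. The treatment labels separate the groups, with DSS alone for 3 samples and DSS with DCA for 3. What the DSS group received in place of the DCA enema is not given in the sources used here. The labels name colonic tissue as the source and intestinal epithelial cells as the cell type, and the libraries held transcripts of muscle, nerve and immune cells as well as of epithelium. The table listed 36977 genes in FPKM, of which 14611 had a mean of at least 0.5 FPKM and were tested. The steps between low values implied 15300000 to 18400000 fragments per library, as an estimate. The labels do not tie libraries to separate mice, so the p-values below measure the spread between these libraries, part of which may be technical.

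The libraries differed within the groups. DSS replicate 4 lay at the mean of DSS replicates 1 and 2. Over 1116 protein-coding genes with a mean of at least 30 FPKM, its median absolute log2 deviation from their best weighted mean was 0.047, against 0.21 between DSS replicates 1 and 2 themselves. The deviation of DSS+DCA replicate 4 from its own 2 group members was 0.24, where these differed by 0.75. The smooth muscle myosin Myh11, chosen after its values were seen, measured 1.07 FPKM in DSS replicate 1, 38.7 in DSS replicate 2 and 20.6 in DSS replicate 4, beside a mean of 19.9 for the first 2. Mitochondrial transcripts made up 29.4% to 31.4% of the summed FPKM in the DSS libraries and 30.5% in DSS+DCA replicate 1, but 47.6% and 46.7% in DSS+DCA replicates 2 and 4. Protein-coding genes outside the mitochondrial genome held 44.8% to 46.0% of the sum in the first 4 of these libraries, and 20.9% and 24.2% in DSS+DCA replicates 2 and 4.

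**Figure D1:**
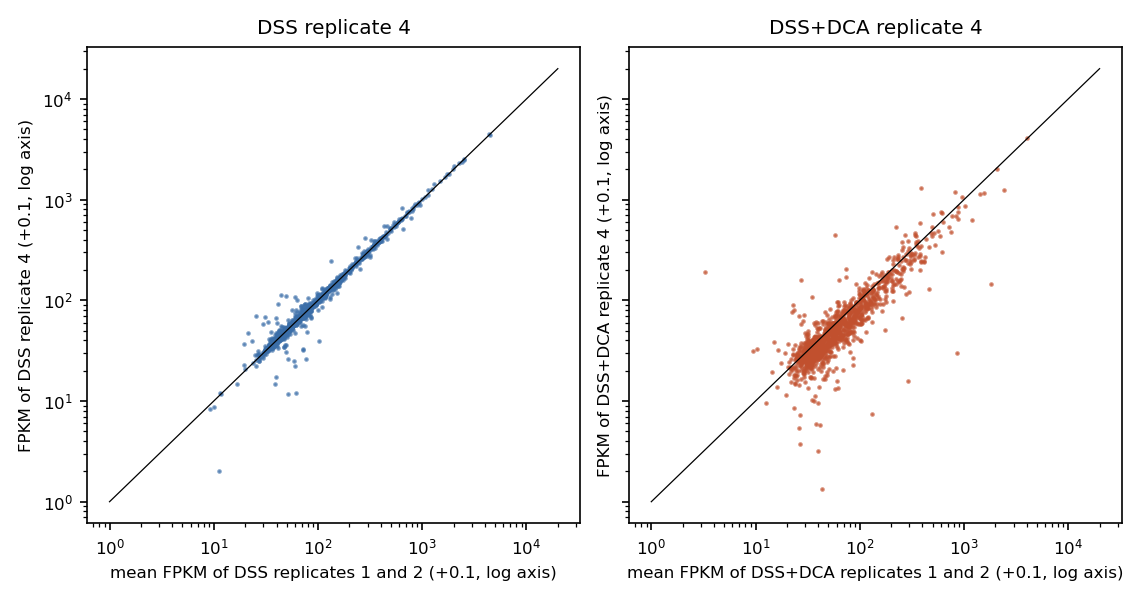
FPKM of replicate 4 (y axis, log scale, 0.1 added) against the mean FPKM of replicates 1 and 2 of the same group (x axis, log scale, 0.1 added) for 1116 protein-coding genes, with the DSS group on the left and the DSS+DCA group on the right and the line of equality in black. DSS replicate 4 deviated from the best weighted mean by a median absolute log2 value of 0.047 and DSS+DCA replicate 4 by 0.24, while replicates 1 and 2 differed by 0.21 in DSS and 0.75 in DSS+DCA.

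The comparison asked how DCA changed colonic gene expression in colitis. The resistin-like molecule Retnlb, a goblet cell product, fell from 1182 ± 179.9 to 106 ± 56.3 FPKM (SD, n = 3 in each group), which was 11.1-fold lower. The water channel Aqp4 fell 14.3-fold, the colonic enteroendocrine hormone Insl5 15.1-fold, and Agr2, a disulfide isomerase needed for mucin folding, 5.62-fold. Nr1d1, a transcriptional repressor of the circadian clock, rose from 5.09 ± 0.897 to 21.6 ± 6.27 FPKM. In all, 82 genes passed an adjusted p under 0.05 in limma, 19 higher and 63 lower with DCA. Each of the 82 changed at least 2-fold on the fitted scale and separated the 3 DSS from the 3 DSS+DCA libraries without overlap. Over all tested genes, 3454 (23.6%) separated the groups in this way, where chance gives 10% if all 6 libraries are exchangeable. DSS replicate 4 lay at the mean of DSS replicates 1 and 2, so the 10% may be too low a baseline. The excess over it is therefore uncertain.

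With predicted genes passed over, the genes that rose most included Rere, Nedd9, Nr1d1, Hbb-bt, Cyp2d26, Pip5k1c, Edn1, C3 and Rab28. Nr1d1 had a log2 change of 1.86 ± 0.25 (SE, adjusted p = 0.0347, limma). Complement component C3 rose 4.32-fold from 1.33 ± 0.0748 FPKM, and the vasoconstrictor peptide gene Edn1 rose 4.81-fold from 0.977 ± 0.244 FPKM. The cytochrome P450 gene Cyp2d26 had the highest level of these, 20.7 ± 3.09 in DSS and 68.2 ± 16.99 in DSS+DCA. The 10 that fell most, with predicted genes passed over and a mean of at least 1 FPKM in DSS, were Aqp4, Retnlb, Hoxa11os, Hoxa13, Insl5, Hoxa9, Thbs4, Hoxa10, Agr2 and Ccn3. Aqp4 had a log2 change of -3.58 ± 0.29 (SE, adjusted p = 0.0169) and Retnlb of -3.57 ± 0.37 (SE, adjusted p = 0.0266). The matricellular protein genes Thbs4 and Ccn3 fell 8.52-fold and 6.62-fold, from 17.8 ± 4.52 and 16.6 ± 3.33 FPKM. In GRCm38, by the gene models of GENCODE M21, Retnlb lies on chromosome 16 from 48816856 to 48818892 and Aqp4 on chromosome 18 from 15389496 to 15410982. The authors' build is not given in the sources used here, and these positions were taken by matching the gene identifiers of the table.

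**Figure D2:**
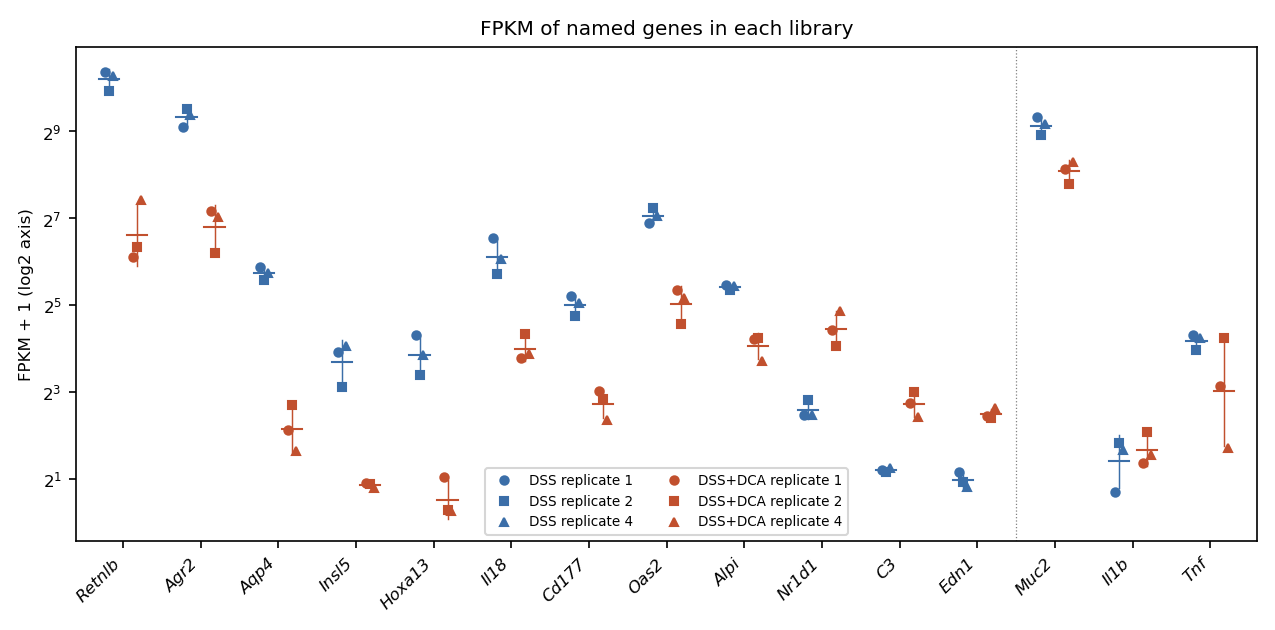
FPKM + 1 (y axis, log2 scale) of 15 named genes in each of the 6 libraries, with DSS in blue and DSS+DCA in red, marker shapes for replicates 1, 2 and 4, a horizontal line at the mean and a vertical line for the SD of the log2 values. The 12 genes left of the dotted line passed an adjusted p under 0.05 and do not overlap between groups, while Muc2 (adjusted p = 0.115), Il1b (0.725) and Tnf (0.371) on the right did not pass.

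The calls depended on single libraries. Without DSS replicate 4, limma called 0 genes at an adjusted p under 0.05 and 1412 at an unadjusted p under 0.05. All 82 genes kept their sign there, which their separation of the groups fixed in advance. Their unadjusted p in limma was at most 0.00288. They had been chosen for small p-values with these same libraries, so this is not separate support. Without DSS replicate 1 it again called 0 (1503 unadjusted), without DSS replicate 2 it called 17, and without DSS+DCA replicates 1, 2 and 4 it called 1246, 171 and 10. The median log2 change of all tested genes was -0.09. A TMM-style scaling moved it by 0.11 and called 118 genes, 32 higher and 86 lower, 69 of them among the 82. Rescaling to the protein-coding genes outside the mitochondrial genome, chosen after seeing the data, moved the median to 0.23 and turned the balance of the calls to 78 higher and 45 lower out of 123, with 54 of the 82 among them.

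Goblet cell markers were lower with DCA as a group. All 21 tested members had lower fitted values, with a median log2 change of -1.11, or -1.02 relative to the median of all genes. Retnlb, Agr2 and Creb3l1, a transcription factor of secretory cells, fell, and 18 members did not pass. Creb3l1 went from 57.7 ± 4.58 to 19.7 ± 3.64 FPKM (adjusted p = 0.0347, and 0.0508 with TMM-style scaling). The mucin gene Muc2, the main component of colonic mucus, measured 564 ± 80.1 and 273 ± 46.4 FPKM (adjusted p = 0.115), and Ang4, an antimicrobial ribonuclease, 8.81 ± 0.438 and 2.26 ± 1.18 FPKM (adjusted p = 0.0678). Adjusted over the list alone, 14 members fell. Camera placed the list lower than other genes (adjusted p = 3.21e-09 with a preset correlation of 0.01, adjusted p = 0.795 with an estimated correlation). Its median was -0.71 after the protein-coding rescaling, or -0.94 against all genes.

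Mature absorptive colonocyte markers were also lower. All 27 tested members had lower fitted values (median log2 change -0.87), 1 fell over all genes tested and 11 fell adjusted over the list alone. The member that fell was Alpi, an intestinal alkaline phosphatase, from 42.2 ± 1.79 to 16.0 ± 3.29 FPKM (adjusted p = 0.0486, and 0.0504 with TMM-style scaling). The carbonic anhydrases Car2 and Car4 measured 421 ± 4.77 against 153 ± 49.9 FPKM and 329 ± 59.4 against 127 ± 28.2 FPKM, each with an adjusted p = 0.0782. Camera gave the list an adjusted p = 3.95e-09 with the preset correlation and adjusted p = 0.795 with an estimated correlation. Its median was -0.42 after the protein-coding rescaling (-0.65 against all genes) and -0.49 with quantile normalization. General epithelial markers had 13 of 15 tested members lower (median -0.73, camera adjusted p = 0.000356, adjusted p = 0.795 with an estimated correlation, in a range of 3.89e-06 to 0.102 over 14 alternatives, the highest with quantile normalization), with 0 past the test over all genes and 5 that fell adjusted over the list alone. Their list mean was 7.53 log2 units in DSS+DCA replicate 1, close to the 7.57 to 7.78 of DSS, and 6.84 in both libraries with the higher mitochondrial share, DSS+DCA replicates 2 and 4. The median was -0.28 after the protein-coding rescaling (-0.51 against all genes) and -0.25 with quantile normalization. Krt19, an epithelial keratin, measured 1668 ± 204 and 796 ± 164 FPKM (adjusted p = 0.121).

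The epithelial antimicrobial and host defence list had 16 of 21 tested members lower and a median of -1.12 (camera adjusted p = 0.00802, adjusted p = 0.795 with an estimated correlation). No member passed over all genes, and 6 fell adjusted over the list alone. The acute-phase gene Saa1 measured 243 ± 86.5 and 38.9 ± 19.2 FPKM (adjusted p = 0.0651), and Duoxa2, the maturation factor of an epithelial oxidase, 188 ± 52.3 and 36.1 ± 24.5 FPKM (adjusted p = 0.0865). The lectin Reg3g spread widely, with 104, 479.7 and 15.7 FPKM in DSS+DCA replicates 1, 2 and 4 against 362 ± 26.6 in DSS (adjusted p = 0.402). Without DSS+DCA replicate 1 the call of this list was lost (adjusted p = 0.257, the highest of 14 alternatives, the lowest being 1.03e-06), and its median was -0.67 after the protein-coding rescaling, -0.68 with quantile normalization and -0.72 with no filter. In the ion and water transport list, Aqp4 fell and 20 of 21 tested members did not pass, with 18 lower fitted values, a median of -0.33 and 3 that fell adjusted over the list alone (camera adjusted p = 0.00802, adjusted p = 0.795 with an estimated correlation, and 0.0798 without DSS+DCA replicate 2, in a range of 0.000176 to 0.0798 over 14 alternatives). Aqp8, a water channel of surface colonocytes, measured 337 ± 25.0 and 71.1 ± 76.0 FPKM (adjusted p = 0.135). The transport list shares Slc26a3, Slc9a3, Scnn1b, Scnn1g and Aqp8 with the colonocyte list, and Best2 and Clca1 with the goblet cell list. The tight junction list shares Cldn7 with the general epithelial list, so the calls of these lists are not independent. Tight junction genes had 15 of 19 tested members lower (median -0.43, camera adjusted p = 0.0399, adjusted p = 0.795 with an estimated correlation), 0 past the test over all genes and 1, Marveld3, that fell adjusted over the list alone, with a log2 change of -0.90 ± 0.16 (SE, adjusted p = 0.0711 over all genes). The tight junction list mean was 4.57 in DSS+DCA replicate 1, above the 4.31 to 4.43 of DSS, and 3.78 and 3.90 in DSS+DCA replicates 2 and 4. Tjp1 had a log2 change of -0.29 ± 0.20 (SE, adjusted p = 0.490) and Ocln of -0.68 ± 0.31 (SE, adjusted p = 0.335). The tight junction list was called in 8 of 14 alternatives, with an adjusted p from 0.000194 to 0.373. Among the losses were those without DSS replicates 1 and 4 (adjusted p = 0.128 and 0.0582), without DSS+DCA replicates 2 and 4 (0.0918 and 0.169) and with quantile normalization (0.373). After the protein-coding rescaling the medians of the transport and tight junction lists turned to 0.02 and 0.01, or -0.20 and -0.22 relative to the median of all genes. Over 14 alternatives they ranged from -0.72 to 0.02 and from -0.60 to 0.01. In the main fit the medians of both lists fell by less than the -0.73 of general epithelial markers. No change in these lists beyond that of the epithelial markers was shown, nor was a change in the share of epithelium itself.

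Enteroendocrine markers were not called as a list (camera adjusted p = 0.262, but 0.00303 with no filter and 0.00997 after the protein-coding rescaling, lower in both), and 2 of 14 tested members fell, which was also the count adjusted over the list alone. These were Insl5 and Gcg, the proglucagon gene, which went from 13.7 ± 0.603 to 4.38 ± 0.997 FPKM (adjusted p = 0.0347). Pyy, another hormone of these cells, measured 83.2 ± 9.07 and 34.6 ± 21.2 FPKM (adjusted p = 0.233).

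Interferon-stimulated genes formed a further low group, with 26 of 27 tested members lower and a median of -0.99. The antiviral genes Oas2 and Mx1 fell, and 25 members did not pass. Oas2, an oligoadenylate synthetase, went from 134 ± 15.7 to 32.6 ± 8.85 FPKM (log2 change -2.03 ± 0.25 SE, adjusted p = 0.0347), and Mx1 from 18.7 ± 2.80 to 5.80 ± 1.17 FPKM. Isg15, a ubiquitin-like modifier, measured 918 ± 72.6 and 187 ± 124 FPKM (adjusted p = 0.0848). Adjusted over the list alone, 17 members fell. Camera gave an adjusted p = 6.68e-09 with the preset correlation and adjusted p = 0.795 with an estimated correlation. The DSS+DCA libraries with the higher mitochondrial shares, replicates 2 and 4, had list means of 3.67 and 3.76 on the log2 scale, and replicate 1 had 4.51, against 4.96 to 5.10 in DSS. The median was -0.59 after the protein-coding rescaling, or -0.82 against all genes. In the main fit the goblet cell (-1.11), colonocyte (-0.87), antimicrobial (-1.12) and interferon (-0.99) medians lay below the -0.73 of general epithelial markers. The SD of the epithelial markers was 0.38 over 15 genes. Whether these lists changed beyond the epithelial markers was not tested.

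Among inflammatory cytokines, Il18, a cytokine made by epithelial cells and released by inflammasomes, fell from 70.2 ± 20.5 to 15.3 ± 3.51 FPKM (adjusted p = 0.0347, and 0.0585 with TMM-style scaling). The other 7 of 8 tested cytokines did not pass, and the list had a camera adjusted p = 0.950. Adjusted over the list alone, Il18 fell and Il33, an alarmin, rose by a log2 change of 1.04 ± 0.23 (SE, adjusted p = 0.116 over all genes). Tnf measured 17.1 ± 2.21 and 9.42 ± 8.03 FPKM (adjusted p = 0.371), and Il1b 1.81 ± 1.03 and 2.27 ± 0.883 FPKM (adjusted p = 0.725). Il6 was below the filter at 0.104 ± 0.0981 and 0.206 ± 0.232 FPKM. The inflammasome and pyroptosis list had 18 of 20 tested members lower (median -0.46) and none past the test, either over all genes or adjusted over the list alone. The adaptor Pycard measured 80.3 ± 0.619 and 46.0 ± 7.55 FPKM (adjusted p = 0.127). Camera gave this list an adjusted p = 0.00968 (adjusted p = 0.795 with an estimated correlation), and the call was lost without DSS replicate 1 (0.0745), without DSS+DCA replicate 1 (0.151) and with quantile normalization (0.499), in a range of 0.000175 to 0.499 over 14 alternatives. Its median was -0.02 after the protein-coding rescaling (-0.25 against all genes) and -0.13 with quantile normalization. In the main fit the median fell by less than the -0.73 of general epithelial markers. A change of this list beyond that of the epithelial markers was not shown. Chemokines had 10 of 21 tested members higher and 11 lower, 1 that fell adjusted over the list alone, and a camera adjusted p = 0.662.

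Neutrophil and macrophage markers were not called as lists (camera adjusted p = 0.429 and 0.377), and the neutrophil list was lower without DSS+DCA replicate 2 (0.0401). The glycoprotein Cd177 fell from 31.6 ± 5.10 to 5.82 ± 1.53 FPKM (adjusted p = 0.0266) and was the 1 of 5 tested neutrophil markers to pass, also adjusted over the list alone. The neutrophil calprotectin genes were low in both groups, with S100a8 at 1.72 ± 1.08 and 2.37 ± 2.28 FPKM (adjusted p = 0.921) and S100a9 at 4.37 ± 3.06 and 4.24 ± 1.75 FPKM (adjusted p = 0.934). Cd177 measured 36.3 and 26.2 FPKM in DSS replicates 1 and 2, where S100a9 measured 1.40 and 7.51. The fall of Cd177 was thus not shown to reflect neutrophils. Of the 15 tested macrophage markers, 0 passed over all genes and 1 fell adjusted over the list alone.

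The unfolded protein and integrated stress response list had 17 of 19 tested members lower (median -0.34, camera adjusted p = 0.00109, adjusted p = 0.795 with an estimated correlation). Atf3, a stress-induced transcription factor, fell from 35.4 ± 3.70 to 13.5 ± 1.64 FPKM (adjusted p = 0.0364) and Sdf2l1, an endoplasmic reticulum protein, from 26.6 ± 0.537 to 9.81 ± 2.11 FPKM (adjusted p = 0.0447). Another 17 did not pass, and 5 fell adjusted over the list alone. The nuclear-encoded respiratory chain list had 24 of 25 tested members lower (median -0.57, camera adjusted p = 0.000356) and the cholesterol biosynthesis list 19 of 22 (median -0.46, camera adjusted p = 0.0194), each with an adjusted p = 0.795 with an estimated correlation, with 0 members of either past the test over all genes, and 3 and 0 adjusted over the list alone. In DSS+DCA replicate 1 the respiratory chain list mean was 6.53, within the 6.41 to 6.57 of DSS, and the cholesterol list mean 3.76, above the 3.63 to 3.71 of DSS. In DSS+DCA replicates 2 and 4 they were 5.51 and 5.78, and 3.33 and 2.78. The stress response list mean was 3.98, 3.36 and 3.31 in DSS+DCA replicates 1, 2 and 4 and 4.08 to 4.11 in DSS. Cox5b, a subunit of cytochrome c oxidase, measured 245 ± 24.4 and 125 ± 28.0 FPKM (adjusted p = 0.135), and Ebp, an enzyme of sterol synthesis, 27.4 ± 1.64 and 14.7 ± 3.57 FPKM (adjusted p = 0.135). The cholesterol list was called in 10 of 14 alternatives. Among the losses were those without DSS replicate 1 (0.0555) and without DSS+DCA replicate 4 (0.360). Quantile normalization ended the cholesterol call (0.0636) and that of the respiratory chain (0.373). Over 14 alternatives the adjusted p ranged from 4.85e-05 to 0.360 for cholesterol biosynthesis and from 6.53e-08 to 0.373 for the respiratory chain. The cholesterol median was -0.05 after the protein-coding rescaling (-0.28 against all genes), and the respiratory chain median -0.13 (-0.36 against all genes) and -0.11 with quantile normalization. Over 14 alternatives the medians ranged from -0.76 to -0.05 for cholesterol biosynthesis and from -0.88 to -0.11 for the respiratory chain. After the protein-coding rescaling the median of the stress response list turned to 0.02, which was -0.21 against all genes, and over 14 alternatives it ranged from -0.72 to 0.02. In the main fit the stress response, respiratory chain and cholesterol medians fell by less than the -0.73 of general epithelial markers. For these lists too, no change beyond that of the epithelial markers was shown. Among fatty acid oxidation and PPAR targets, the fatty acid transporter Cd36 rose from 0.167 ± 0.0404 to 1.41 ± 0.154 FPKM (adjusted p = 0.0347), which was also the 1 call adjusted over the list alone. The other 24 of 25 tested members did not pass (camera adjusted p = 0.795).

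Smooth muscle and enteric neuron and glia markers were higher with DCA as lists, with a wide spread between libraries. All 16 tested smooth muscle markers (median 1.26) and all 19 tested enteric neuron and glia markers (median 1.02) had higher fitted values, and 0 passed over all genes or adjusted over the list alone. The smooth muscle list mean was 1.83, 4.63 and 3.79 log2 units in DSS replicates 1, 2 and 4 and 5.87, 2.52 and 5.24 in DSS+DCA replicates 1, 2 and 4, so the groups overlapped. The neuron and glia list mean was 0.27, 1.40 and 0.91 in the DSS and 2.96, 0.69 and 2.26 in the DSS+DCA libraries, which overlapped too. Gfap, an intermediate filament gene of enteric glia, measured 0.726 ± 0.657 and 4.34 ± 3.04 FPKM (adjusted p = 0.259), and Pgm5, a muscle gene, 2.41 ± 2.22 and 13.1 ± 11.8 FPKM (adjusted p = 0.370). Camera gave adjusted p-values of 0.000566 and 5.35e-08 with the preset correlation and an adjusted p = 0.795 for both lists with an estimated correlation. The smooth muscle call was lost without DSS replicate 1 (0.0569) and after the protein-coding rescaling (0.239), in a range of 1.15e-07 to 0.239 over 14 alternatives. The medians ranged from 0.24 to 2.38 for smooth muscle and from 0.50 to 1.73 for neurons and glia.

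Erythroid genes were higher in all 3 DSS+DCA libraries, where the list mean was 2.34 to 2.99 log2 units against 0.94 to 1.58 in DSS. The beta-globin gene Hbb-bt rose from 0.498 ± 0.168 to 4.44 ± 1.46 FPKM (adjusted p = 0.0347), 3 of 4 tested members did not pass, and all 4 rose adjusted over the list alone (camera adjusted p = 3.12e-06, adjusted p = 0.795 with an estimated correlation). Hbb-bt and Hbb-bs are near-identical copies, so reads may be shared between them and the level of each is uncertain. Adipocyte markers had 8 of 10 tested members higher (median 0.88, camera adjusted p = 0.00112, adjusted p = 0.795 with an estimated correlation), none past the test over all genes and 2 that rose adjusted over the list alone. Cfd, the adipocyte product adipsin, measured 15.7, 112 and 3.70 FPKM in DSS+DCA replicates 1, 2 and 4 and at most 0.781 in DSS (adjusted p = 0.158). T and natural killer cell markers had 11 of 13 tested members higher (median 0.27, camera adjusted p = 0.00389), MHC class II presentation genes 10 of 13 (median 0.22, camera adjusted p = 0.0357) and B and plasma cell markers 9 of 12 (median 0.74, camera adjusted p = 0.0194), with 0 members past the test over all genes or adjusted over the list alone. Each of these 3 lists had an adjusted p = 0.795 with an estimated correlation. Their list means in DSS+DCA replicate 2 were 1.70, 2.75 and 1.54, below all DSS libraries (1.71 to 1.73, 2.79 to 3.30 and 2.19 to 2.36), so the groups did not separate. The T cell kinase gene Lck measured 2.48 ± 0.298 and 4.09 ± 0.285 FPKM (adjusted p = 0.174). In the B and plasma cell list 3 members had lower fitted values, among them the immunoglobulin gene Igkc, at 737 ± 251 and 192 ± 178 FPKM (adjusted p = 0.167). The calls of the MHC class II and B cell lists were lost with TMM-style scaling (adjusted p = 0.0820 and 0.109), without DSS replicate 2 (0.252 and 0.0835) and without DSS+DCA replicate 4 (0.0958 and 0.603). Without DSS+DCA replicate 1 the MHC class II call was lost too (0.253), and its median turned to -0.12. The adipocyte call was lost with array weights (0.0897, the highest of 14 alternatives from 8.43e-06) and the T and natural killer cell call with a mean of at least 2 FPKM (0.0891, the highest of 14 from 0.00186). Over 14 alternatives the adjusted p ranged from 0.00283 to 0.255 for MHC class II and from 8.13e-07 to 0.719 for B and plasma cells, and each was called in 7 of the 14. The medians ranged from 0.81 to 2.08 for erythroid, 0.26 to 1.83 for adipocyte, 0.05 to 0.57 for T and natural killer cell, -0.12 to 0.64 for MHC class II and 0.47 to 1.65 for B and plasma cell genes.

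**Figure D3:**
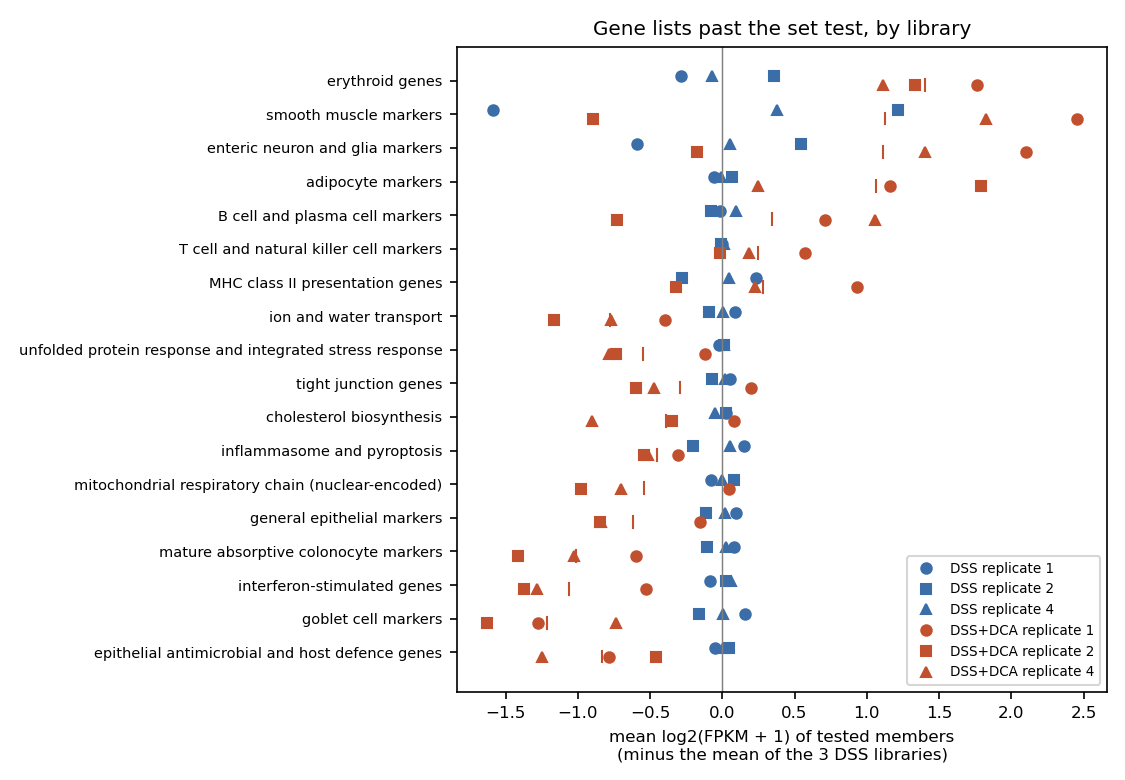
Mean log2(FPKM + 1) over the tested members of each of the 18 gene lists past camera's adjusted p under 0.05 with the preset correlation, minus the mean of the 3 DSS libraries (x axis, log2 units), with DSS in blue, DSS+DCA in red, a marker shape per replicate and a red bar at the DSS+DCA mean. The goblet cell, colonocyte and interferon lists lie below the DSS libraries in all 3 DSS+DCA libraries, while the smooth muscle, neuron and glia, B cell, T cell, MHC class II, tight junction, respiratory chain and cholesterol lists do not separate the groups. The smooth muscle list had means of 5.87, 2.52 and 5.24 in DSS+DCA against 1.83, 4.63 and 3.79 in DSS.

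Of the fibroblast and extracellular matrix list, the proteoglycan gene Dcn rose from 1.20 ± 0.410 to 4.50 ± 0.609 FPKM (adjusted p = 0.0486), which was also the 1 call adjusted over the list alone, and 21 of 22 tested members did not pass (camera adjusted p = 0.135). Endothelial markers had 7 of 9 tested members higher (camera adjusted p = 0.0514), with 0 calls. Each of these 2 lists was called higher in 5 of 14 alternatives, with array weights at an adjusted p of 0.000764 for fibroblasts and 8.02e-05 for endothelium. The fibroblast list was also called with a mean of at least 2 FPKM (0.00324), and over the alternatives the adjusted p went up to 0.923 and 0.870.

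The genes of bile acid sensing and transport were not called as a list (16 tested, camera adjusted p = 0.422), none passed over all genes and 3 fell adjusted over the list alone. Nr1h4, which encodes the bile acid receptor FXR, measured 81.4 ± 3.31 and 82.8 ± 21.3 FPKM (log2 change -0.01 ± 0.24 SE, adjusted p = 0.987), and its fitted change was 0.15 with TMM-style scaling. The basolateral transporter subunits Slc51a and Slc51b measured 10.96 ± 2.22 against 39.2 ± 34.6 FPKM (adjusted p = 0.310) and 205 ± 5.98 against 87.3 ± 29.3 FPKM (adjusted p = 0.102). Gpbar1, the membrane bile acid receptor, was below the filter, at most 0.271 FPKM in DSS and 0.202 in DSS+DCA, and listed at 0 in DSS replicate 1 and DSS+DCA replicate 2. The hormone gene Fgf15 was at most 0.0401 FPKM in DSS and listed at 0 in DSS+DCA replicates 1 and 4.

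Stem cell and Wnt target genes (adjusted p = 0.415) and cell cycle genes (0.988) were not called as lists in camera. Mki67, a proliferation marker, measured 14.3 ± 5.24 and 9.76 ± 2.71 FPKM (adjusted p = 0.469), and the stem cell marker Lgr5 was below the filter at 0.423 ± 0.121 and 0.308 ± 0.0867 FPKM. No camera call was made for tuft cell (0.385), mast cell and eosinophil (0.988), NRF2 (0.272), p53 and apoptosis (0.702), injury-associated epithelial (0.157), xenobiotic metabolism (0.294), squamous (0.473), skeletal muscle (0.283), and pancreas and liver lists (0.226). Alternatives called some of them lower, with no filter NRF2 (0.0148), xenobiotic metabolism (0.0148) and injury-associated genes (0.0284, and 0.00947 after the protein-coding rescaling), with array weights cell cycle genes (0.0250), and without DSS+DCA replicate 4 pancreas and liver genes (0.0437). None of their members passed over all genes. Adjusted over the list alone, 2 injury-associated, 1 p53 and 1 pancreas and liver genes fell and 1 squamous gene rose. The median, mean and camera direction differed in sign for the chemokine, macrophage, stem cell, mast cell, cell cycle, fatty acid oxidation and distal position lists, none of which was called. Of the sex-linked genes only Xist was tested, at 43.7 ± 0.394 and 35.2 ± 2.18 FPKM (adjusted p = 0.384).

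A run of neighbouring transcripts in the Hoxa cluster, which encodes transcription factors of position along the body axis, fell together. All 10 tested Hoxa genes had lower fitted values, and 3 of them fell past the threshold. Hoxa7, named after its values were seen, measured 39.5 ± 4.96 and 10.5 ± 6.61 FPKM (adjusted p = 0.0865). Hoxa13 went from 13.9 ± 4.71 to 0.498 ± 0.494 FPKM (log2 change -3.32 ± 0.31 SE, adjusted p = 0.0252), Hoxa9 from 13.8 ± 2.02 to 1.09 ± 0.294 FPKM (log2 change -2.83 ± 0.19 SE, adjusted p = 0.0102) and Hoxa10 from 15.1 ± 0.539 to 1.97 ± 1.26 FPKM (log2 change -2.55 ± 0.35 SE, adjusted p = 0.0364). The antisense transcript Hoxa11os fell 21.9-fold, from 21.1 ± 9.96 FPKM, while Hoxa11 on the opposite strand measured 3.15 ± 2.03 and 2.46 ± 1.77 FPKM (adjusted p = 0.797). The authors' use of strand in counting is not given in the sources used here. With 3 short RNAs inside Hoxa11os, which are not independent of it, and 1 unnamed transcript, 8 features that fell lay within 37.8 kb of chromosome 6, from 52223100 to 52260880 in GRCm38 by the gene models of GENCODE M21. None of the 13 tested genes of the Hoxb and Hoxd clusters passed, and no Hoxc gene met the filter. Unlike the Hoxa genes, all of the 13 except Hoxb9 and Hoxd4 (log2 changes -0.04 and -0.14) had higher fitted values. With TMM-style scaling Hoxa5, Hoxa6 and Hoxb7, named after their values were seen, passed too (adjusted p = 0.0447, 0.0484 and 0.0487), with 22.6 ± 2.55 against 6.27 ± 3.14 FPKM for Hoxa5, 2.04 ± 0.512 against 0.343 ± 0.0740 FPKM for Hoxa6 and 6.75 ± 1.88 against 15.0 ± 2.39 FPKM for Hoxb7. Hoxd9 measured 0.435 ± 0.292 and 3.55 ± 1.99 FPKM (adjusted p = 0.141). The list of distal hindgut position genes held Hoxa13 as its 1 call among 4 tested members (camera adjusted p = 0.520). Adjusted over the list alone, 2 members rose, Hoxd9 and Hoxd10, and 1 fell. Its median was 0.62 and its mean -0.09.

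**Figure D4:**
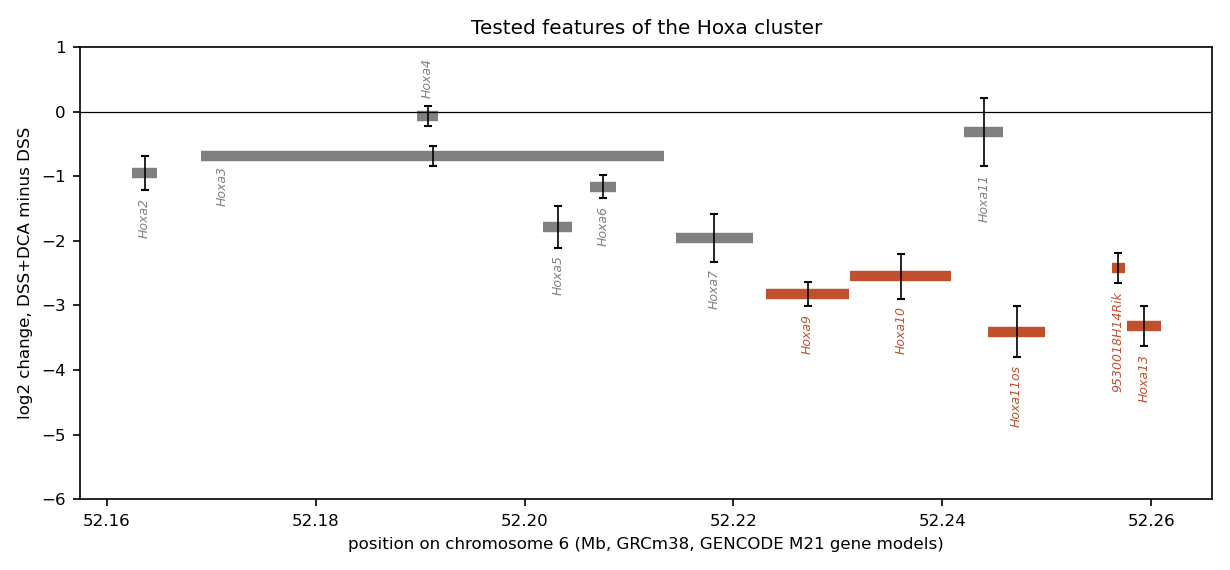
Log2 change (DSS+DCA minus DSS, y axis, on the log2(FPKM + 1) scale) of tested features of the Hoxa cluster against their position on chromosome 6 (x axis, Mb, GRCm38), with each bar spanning the gene and black whiskers giving the SE. Features past an adjusted p under 0.05 are red and the others grey, and 3 short RNAs inside Hoxa11os are not drawn. The log2 changes of Hoxa9, Hoxa10 and Hoxa13 were -2.83, -2.55 and -3.32 with all 6 libraries, against -0.32 for Hoxa11, which turned to 0.47 with array weights.

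The authors' deposited table marked 1174 genes as significant, 808 up and 366 down. In the authors' deposited table, this mark was given exactly where q was under 0.05 and the change at least 2-fold, and 486 of the marked genes, 455 of them up, had a mean under 0.5 FPKM and were outside the test used here. Among the genes tested here, the authors' deposited table marked 688, 353 up and 335 down, where the test used here called 19 higher and 63 lower. Of the 82 genes called here, 80 were among these 688, all 80 with the same sign. Both sets of calls come from the same 6 libraries, so the overlap is not independent support.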

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

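Rescaling to protein-coding genes and the overlap counts under the alternatives were chosen after seeing the data. The 82 calls became 2 with no filter (0 higher, 3770 genes at an unadjusted p under 0.05 in limma), 6227 with array weights, which gave DSS replicate 4 a weight of 8.08, and 230 at an adjusted p under 0.1. Leaving out single libraries gave 0 (without DSS replicates 1 and 4) to 1246 (without DSS+DCA replicate 1). The 80 calls shared with the authors' deposited table became 2 with no filter, 655 with array weights, and 0 to 307 without single libraries. A minimum fold of 2 left 82 calls, a pseudocount of 0.1 gave 68, a mean of at least 2 FPKM 99 and quantile normalization 93, within 1.5 times the main count. With no filter 36977 genes were tested, and without a library fewer samples; the cause was not tested otherwise. Camera with an estimated correlation called 0 of the 18 lists (smallest adjusted p = 0.795). Replicate numbers did not pair the samples, with correlations of -0.144, -0.170 and 0.0153 and 0 samples closest to their own number. With the replicate block limma called 1 gene (1835 at an unadjusted p under 0.05), shared by 1 authors' call, and all 18 list calls were kept. The planned edgeR and DESeq2 alternatives were not run because the table holds FPKM.

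Of 1196 values for 86 named genes under the alternatives, 827 kept direction and side of the threshold, 264 lost the call, 79 gained one and 26 turned sign. Of 270 values for the 18 lists, 217 were kept and 53 lost, and none turned camera's direction. The log2 changes that turned sign had not passed, and the cause was not tested. Without single libraries they ranged from -0.38 to 0.70 for S100a8, -0.39 to 0.52 for S100a9, -0.68 to 0.21 for Hoxa11, -0.082 to 0.48 for Il1b, -0.17 to 0.21 for Nr1h4, -0.39 to 0.28 for Nfil3 and -0.13 to 0.019 for Hoxb9. With array weights they were -0.15 for S100a9, 0.47 for Hoxa11, -0.15 for Clock and -0.0076 for Il1b. With TMM-style scaling they were 0.15 for Nr1h4 and 0.12 for Hoxb9, with quantile normalization 0.44 for Nr1h4, 0.10 for Xist and 0.34 for Hoxb9, and with protein-coding rescaling 0.43 for Nr1h4, 0.11 for Tjp1, 0.13 for Xist, 0.22 for Nfil3 and 0.40 for Hoxb9.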

Other observations

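The tests of enrichment and of explanations for DSS replicate 4, the Hoxa genes and the circadian genes were chosen after the result was seen, while the limma fits, with all and without single libraries, and the count over other splits were planned. The following called genes lie outside the lists and were named after their values were seen. B3galt5, a galactosyltransferase, fell from 91.5 ± 7.21 to 20.8 ± 5.66 FPKM (SD, n = 3 in each group, limma adjusted p = 0.0330), Nans, a sialic acid synthase, from 54.4 ± 1.24 to 21.6 ± 1.79 FPKM (0.0347), and the membrane mucin Muc4 from 10.4 ± 1.94 to 3.03 ± 0.620 FPKM (0.0370). The sulfotransferase Chst4 and the sialyltransferase St3gal6 fell 3.39-fold and 4.44-fold. The metal-binding protein gene Mt2 fell from 344 ± 110 to 86.7 ± 6.93 FPKM (0.0395). Ifnl3, an interferon lambda gene, fell from 4.06 ± 0.879 to 0.331 ± 0.422 FPKM (0.0347) and Isg20, an antiviral exonuclease, from 10.8 ± 1.86 to 3.85 ± 0.421 FPKM (0.0453). No term passed among 1849 tested for the 50 annotated genes that fell. The smallest adjusted p was 0.133 in the hypergeometric test (unadjusted 0.000112), for hormone activity, with Insl5, Ppy and Retnlb, and equally (unadjusted 0.000144) for negative regulation of viral genome replication, with Ifnl3, Isg20 and Oas2. As with all 82 calls, these were lost without DSS replicate 4 and without DSS replicate 1, where limma called 0 genes (1412 and 1503 at an unadjusted p under 0.05). With TMM-style scaling the limma calls of Chst4, Mt2 and Isg20 were lost too (adjusted p = 0.0539, 0.0507 and 0.0587).

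The real grouping called 82 genes, and the highest of the other splits of the 6 libraries into 3 and 3 called 3, so 1 of 10 splits gave as many. With 10 splits a share under 0.05 cannot be reached.

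DSS replicate 4 lay at the mean of DSS replicates 1 and 2. That a library of a group lies between the other 2 in general cannot be told apart from a feature of this library. The deviation of DSS+DCA replicate 4 was 5.15 times that of DSS replicate 4, but 1.42 times when each was divided by the difference between its pair, and of the genes that differed at least 2-fold between the pair, 83.4% lay between in DSS+DCA and 83.0% in DSS. DSS replicate 4 may hold an equal mixture of the RNA or reads of the other 2. The variance of its deviation was 2.27 times the sampling variance of fragments over 812 genes, and 5.33 to 23.5 times for the other libraries, a value between the bounds set for a mixture and for a separate sample, so these cannot be told apart. If it were a mixture, the DSS group would hold 2 independent libraries, and no biological explanation was tested.

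Posterior Hoxa genes were lower in DSS+DCA, with little change in Hoxa11 (log2 change -0.32). Hoxa5 and Hoxa7, which are not among the posterior genes, had lower fitted values too (-1.78 and -1.95). The median log2 change of the 4 posterior Hoxa genes lay -1.96 from that of the general epithelial markers, whose SD was 0.38 over 15 genes. The Hoxa genes were listed after their fall was seen, so their choice in part fixed this gap. General markers also cannot show the loss of only a part of the epithelium. A lower share of epithelial cells therefore cannot be told apart from other causes. Tissue taken farther from the anus may account for the Hoxa fall, and would lower posterior genes of the other clusters too. The median of those tested was 1.56, but of the 3 tested only Hoxb9 had at least 1 FPKM in both groups, at 32.3 ± 3.65 and 31.3 ± 1.22 FPKM, so the sampling site cannot be told apart from an effect of DCA. Hoxb13, a distal marker below the filter, measured 0.297 ± 0.152 FPKM in DSS and at most 0.0257 in DSS+DCA.

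Circadian genes of opposite phase tended apart. Of 6 tested genes in phase with Nr1d1, itself included, all had higher fitted values, and of 5 of the opposite phase 4 had lower ones. Nr1d1 rose, while Dbp measured 0.938 ± 0.247 and 7.79 ± 5.63 FPKM (adjusted p = 0.124), Tef 0.363 ± 0.452 and 2.34 ± 0.511 FPKM (0.0865) and, of the opposite phase, Cry1 11.2 ± 1.89 and 4.47 ± 0.835 FPKM (0.0673) and Arntl 3.53 ± 0.312 and 1.52 ± 1.05 FPKM (0.203). Also of the opposite phase, Nfil3 measured 4.43 ± 0.477 and 4.32 ± 2.23 FPKM (0.878), and Clock, which had a higher fitted value, 1.45 ± 1.34 and 1.95 ± 0.458 FPKM (0.617). The lists were drawn up after Nr1d1 was seen to rise, so it was left out of their test. This does not remove the selection from genes that follow Nr1d1. The difference between the means of the lists was then 1.61 log2 units, at percentile 99.98 of 10000 random pairs of lists matched on expression. The random genes were picked independently, while genes of a shared phase may move together. The percentile thus measures the choice of genes and not the spread between libraries. A different time of day at collection may account for the difference between the lists, but the labels give no time, so this cannot be told apart from an effect of DCA on the clock.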
